A study of Rattus norvegicus with 5 samples.

How the data were processed

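RNA levels were measured with DNA arrays in soleus, a postural hindlimb muscle, of young female Wistar rats. All 5 samples belonged to 1 condition: the hindlimbs had been unloaded by suspension for 14 days and then bore weight again for 5 days. Per the labels' protocols, total RNA came from frozen sections of the muscle, was purified with an RNeasy kit, and 5 microgram of it was used; these details stand in the label of 1 sample. The labels do not say whether each sample came from a different animal, so measures of spread describe these samples and could include technical variation. Samples of another condition were not analysed here, so no comparison between conditions was made.

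The authors deposited 1 table with an intensity for each of 1185 features on each of the 5 arrays, on a linear scale. Intensities as deposited ran from -40094 to 1766702, with no missing value, and the columns had unequal medians. Values as large as 1766702 show that the deposited intensities were not on a log scale. The unequal medians show that they were not scaled to a common median. Background had been subtracted in some form, judging by the values below 0. The array type, the imaging software, the background method and any scaling are not given in the sources used here. Features carry an ID of the form R or RG and a number. The deposited table does not pair these IDs with genes, and 0 of the 1185 IDs matched an identifier in a RefSeq gene table of the GRCr8 rat assembly. Features are therefore named by ID, and no gene symbol or position is given. Intensities of different features were not compared with each other as levels, because features can bind their targets with different efficiency.

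The analysis used R 4.3.3 and limma 3.58.1, with Python 3.11.15 and matplotlib 3.10.9 for figures. Features above 0 on all 5 arrays were tested, 661 in number. Their intensities were log2 transformed, and each array was centred on its median over these features, because the medians differed by over 5%. Centred intensities are on a common scale set by the mean of the 5 log2 medians. For each feature the mean, the SD of log2 values and the coefficient of variation (CV, the SD over the mean of the centred linear intensities) were computed over the 5 samples. Excess spread was tested with limma: a feature's variance over the prior variance fitted at its mean level, by a one-sided F test, with Benjamini-Hochberg adjustment at 0.05. Intervals of median CVs are 95% bootstrap intervals from 10000 resamples of features, which are not independent replicates. Background noise of an array was taken from the sizes of its values below 0, and the noise bound was their 95th percentile. The number of arrays limits the precision of every value.

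The test was tried on simulated data built on the means of the same 661 features. In these, 5, 20 or 200 features were given 8 times the prior SD, and all others either shared 1 SD at a given level or had spreads made as uneven as in the data. Each setting was drawn 200 times, after a first single draw, and tested with the main and the robust prior. The report gives the mean share of changed features called, with standard errors of at most 1.51 percentage points. In 1 further draw, with 200 changed features of 4 kinds among uneven spreads, it called 0 of 50 at 4 times and 0 of 50 at 8 times the prior SD, and 0 of 50 for each of the shifts of 1 sample by 4 and by 8 log2 units. Data made with 4.16 prior degrees of freedom were fitted with 3.83. In 100 draws with no changed feature and 1 SD at a given level, 44 gave at least 1 call, so the test was not strict at even spreads.

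The design, the test, the gene lists and the rule for named genes were fixed before the data were examined. That rule named only features with a gene name, and it therefore selected 0 features. The 19 gene lists, the cell type marker lists and both planned tests of lists could not be run without gene names. The features named in the text were chosen after their values were seen. In the report these are the 2 features with the highest variance over the prior among those above the noise bound on all arrays, and the 2 with the smallest SD among features above the median level. The closing section also names R369, R370 and R371, which no rule selected: they were picked for their consecutive IDs and like profiles. The alternatives were no centring, quantile normalization, leaving out the dimmest quartile of features, a pseudocount of 155 intensity units (the 10th percentile of values above 0), features above 0 on 3 or 4 arrays, 1 prior variance for all levels, a robust prior, and leaving out each replicate. Cyclic loess, normexp background correction with an offset of 50, and the noise bound as a filter were added after the data were seen. Replicates are numbered in the order of deposit, and the number pairs nothing.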

Results

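The data consisted of 5 array measurements of RNA levels in rat soleus after 14 days of hindlimb suspension and 5 days of reloading. Hindlimb suspension removes the load from the antigravity muscles, the soleus among them, and reloading returns the animal to normal weight bearing. All samples belonged to this condition, so the measurements give the level of each feature in reloaded muscle and the differences between samples, and they do not show a response to suspension or to reloading. The deposited values were intensities that reached below 0, as after background subtraction, and had no common scale, and features are given by array ID because no gene names were paired with them.

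Only a minority of features exceeded a strict noise bound on every array. Of the 1185 features, 661 (55.8%) had an intensity above 0 in all 5 samples and 36 (3.04%) in none of them. A further 220 features were above 0 in 4 samples, 116 in 3, 87 in 2 and 65 in 1. The noise bound, set from the values below 0 on each array, was exceeded on all arrays by 182 features. It lay above the median intensity of the 661 features on every array, as with 8341 against 3871 in replicate 2. The median size of the values below 0 was far smaller, at 204 to 521, so the bound is set by a long tail. An intensity above 0 is a weaker limit, since noise alone can give one. The 36 features above 0 in no sample were not detectable here, which does not show that their transcripts were absent.

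The arrays differed in brightness. The median intensity of the 661 features was 793 in replicate 1, 3871 in replicate 2, 4492 in replicate 3, 2306 in replicate 4 and 2258 in replicate 5, a 5.67-fold range. Replicate 1, the dimmest, had 333 features at or below 0, against 199, 145, 233 and 243 in replicates 2 to 5. Of the 220 features that missed the limit on a single array, 120 missed it in replicate 1. The typical size of the values below 0 was 25.7% of the median intensity in replicate 1 and between 10.6% and 20.5% in the other samples. By the noise bound, replicate 1 did not stand out: 262 features exceeded it there, against 213, 314, 248 and 239 in replicates 2 to 5. In each sample, between 39.0% and 47.5% of the intensity above 0 lay in the 10 brightest features.

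**Figure D1:**
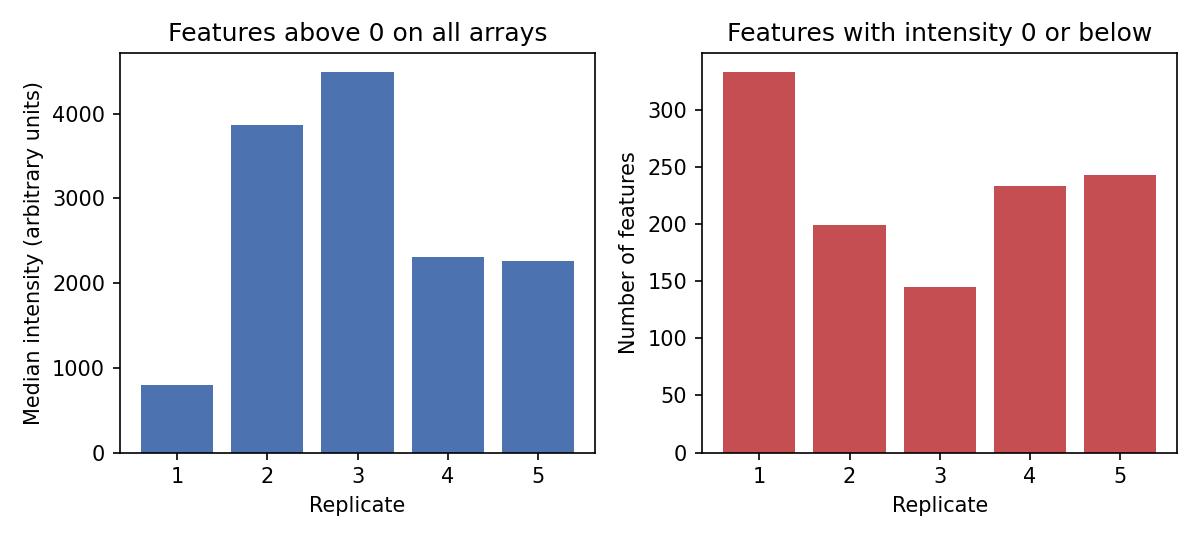
Left, the median intensity in arbitrary units of the 661 features above 0 on all arrays, one bar per replicate. Right, the number of the 1185 features with an intensity of 0 or below; replicate 1 has the lowest median (793) and the most such features (333).

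After centring, the profiles of the 5 samples correlated across features. Pearson's r of log2 intensities over the 661 features ranged from 0.825 to 0.933 over the 10 pairs of samples, with a median of 0.881; these correlations are across features, which are not independent replicates. The 4 lowest values all involved replicate 1, whose mean r with the other samples was 0.843. The mean r of the others lay between 0.876 and 0.904. The closest pair was replicates 3 and 5, whose log2 intensities differed with an SD of 0.97, and the most distant was replicates 1 and 2, with an SD of 1.59. No pair of arrays held the same values.

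The spread between samples was wide, and widest in dim features. The median CV over the 661 features was 38.7% (95% bootstrap interval over features 37.0 to 41.1, n = 5 samples), and the median SD was 0.58 on the log2 scale. The jackknife error of the median CV over samples, from leaving out each sample in turn, was larger, at 5.72 percentage points. In the dimmest quartile of features the median CV was 61.2% (56.7 to 66.5). It was 39.6% (35.1 to 44.2) in the next quartile, 33.2% (30.8 to 35.6) in the one above, and 28.5% (26.2 to 32.3) in the brightest. The SD fitted by limma did not fall throughout: it was lowest, 0.387, at a mean log2 intensity of 14.30 and was 0.619 at the brightest feature (19.72). Among the 182 features above the noise bound on all arrays the median CV was 24.3%, with the arrays centred on these 182 in place of the 661. These values describe the spread of levels over these 5 samples after median centring, and other processing gave other values.

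No feature passed the test of excess spread. With limma's prior variance and Benjamini-Hochberg adjustment, 0 of 661 features had an adjusted p below 0.05, the smallest adjusted p being 0.92. An unadjusted p below 0.05 was found for 33, about the share that this threshold passes by chance. The prior was also fitted to these same variances. The spreads themselves were uneven from feature to feature: limma fitted 4.16 prior degrees of freedom, against at least 11.8 in 100 simulated data sets in which features of like level shared an SD. In 200 simulated data sets per setting, with changed features at 8 times the prior SD and spreads as uneven as in the data, the test called on average 4.6% of 5 changed features, 0.425% of 20 and 0% of 200. With a robust prior these shares were 15.8%, 13.8% and 0%. With a common SD for the rest, the main prior gave 87.0%, 59.7% and 0%, and the robust prior 91.6%, 91.0% and 0%. The count of 0 therefore does not show that the samples were alike. The robust prior also called more unchanged features per simulated data set. With 5 and 20 changed features among uneven spreads it called 0.285 and 0.26 on average, against 0.055 and 0 with the main prior. With a common SD these means were 1.095 and 1.24, against 0.205 and 0.

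**Figure D2:**
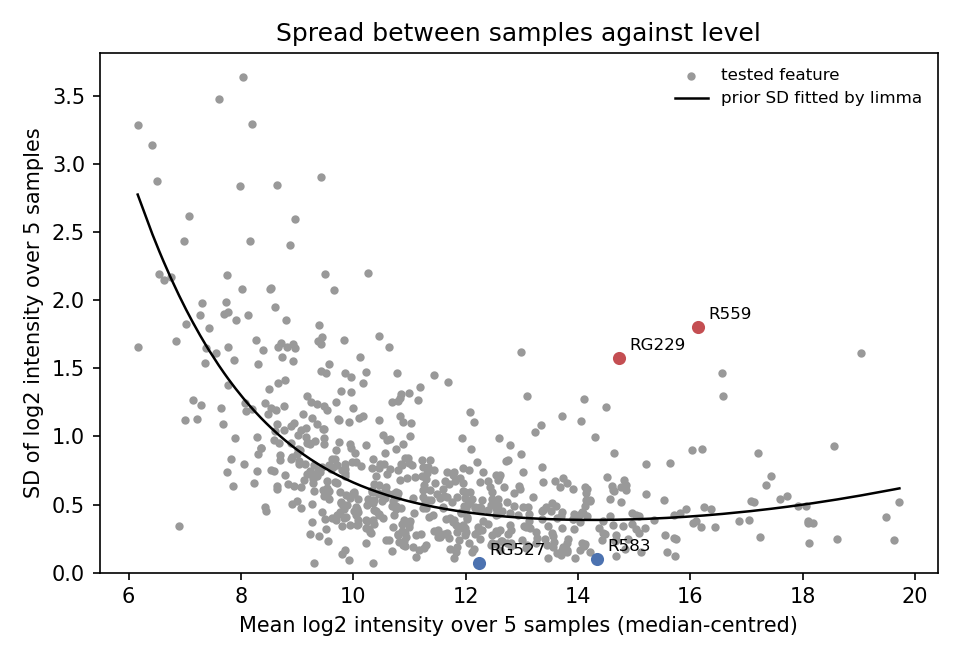
Each grey point is one of the 661 tested features, with its mean log2 intensity (median-centred) on the x axis and the SD of its log2 intensity over 5 samples on the y axis; the line is the prior SD fitted by limma. Spread is widest for dim features, and R559 (SD 1.80) and RG229 (SD 1.58) lie far above the line while RG527 (SD 0.07) and R583 (SD 0.10) lie below it.

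Among features above the noise bound, R559 and RG229 stood farthest above the fitted spread, and neither passed the test (limma, adjusted p = 0.92 for both). R559 had a mean log2 intensity of 16.14 ± 1.80 (SD, n = 5). Its centred intensity was 7755 in replicate 1 and between 113601 and 134311 in replicates 2 to 5, a 17.3-fold difference between the extremes. Its log2 SD was 0.11 without replicate 1 and 2.70 without centring of the arrays. RG229 had a mean log2 intensity of 14.73 ± 1.58 (SD, n = 5) with 2 levels: its centred intensity was 86557 in replicate 1 and 88652 in replicate 5, against 14586, 8517 and 15613 in replicates 2, 3 and 4. As deposited, replicates 1 and 5 were also the highest, with 29189 and 85153 against 24023, 16277 and 15315 in replicates 2, 3 and 4. Replicate 1 was then close to replicate 2, so the 2 levels appeared only after centring. The log2 SD without centring was 0.999.

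The steadiest features among those above the median intensity were RG527 and R583. They were not required to exceed the noise bound, and RG527 was below it in replicate 2. RG527 had a centred intensity of 4848 ± 234 (SD, n = 5), a CV of 4.82%. R583 had 20785 ± 1427 (SD, n = 5), a CV of 6.87%. Both were picked as the smallest of many spreads, and so their values understate the error to be expected of them in further samples. Their log2 SDs of 0.07 and 0.10 became 0.15 and 0.19 after quantile normalization and 0.99 and 0.95 without centring of the arrays. The SD of R583 was 0.059 without replicate 5.

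**Figure D3:**
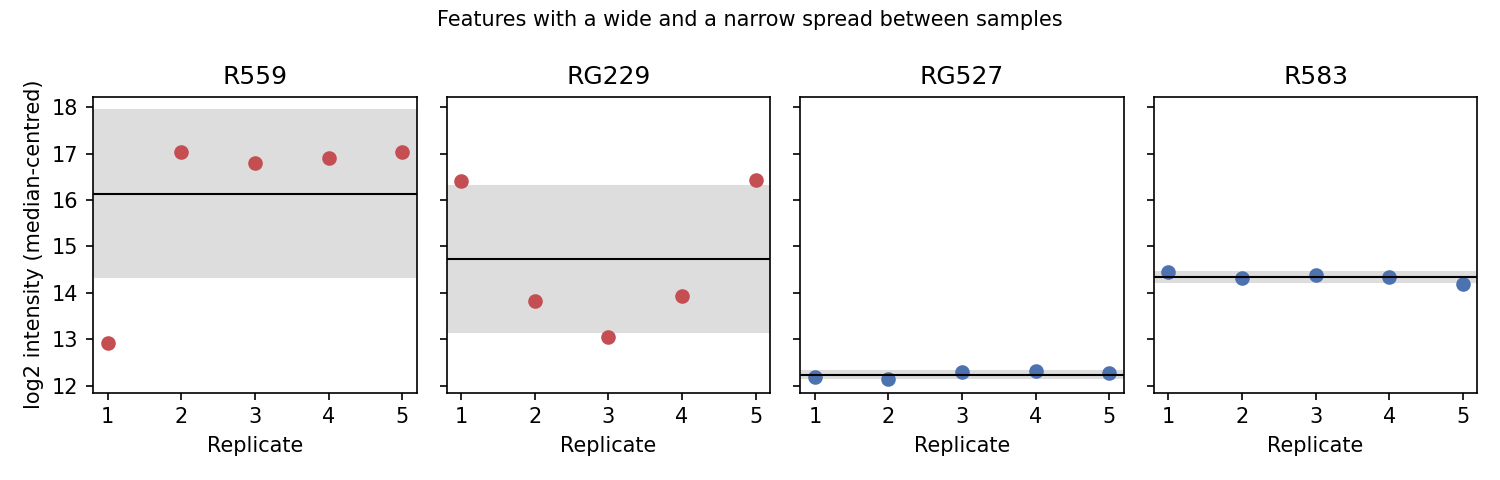
Median-centred log2 intensity of 4 features in each replicate; the line is the mean over 5 samples and the grey band is the mean ± 1 SD. R559 is low in replicate 1 alone, RG229 is high in replicates 1 and 5, and RG527 and R583 vary little.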

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

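The outlier counts over all features were added after the data were seen, and the tests of explanations were set after the array summaries but before their own results were known. Feature R559 was flagged because 1 sample lay far from the other samples: the gap of replicate 1 to its nearest neighbour was 0.941 of the whole log2 range, above Dixon's limit of 0.71 for 5 samples. Chance flags about 5% of such groups, and R559 had been picked for its wide spread. Over all 661 tested features, 92 (13.9%) passed the same limit, and in 50 of them the sample apart was replicate 1; replicates 2 to 5 accounted for 16, 4, 10 and 12. Among the 182 features above the noise bound on all arrays, 20 passed it, 15 of them through replicate 1.

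Replicate 1 differed more from the other samples than they did from each other. The mean SD of log2 differences was 1.51 over the 4 pairs with replicate 1 and 1.14 over the 6 other pairs, an excess of 0.37 (95% bootstrap interval over features 0.26 to 0.48). Over the 5 samples as such, replicate 1 did not pass Dixon's limit of 0.71, with 0.603 for log2 median intensity, 0.479 for features at or below 0, 0.547 for mean r and 0.348 for noise over median intensity. By the typical size of the values below 0, its dimmer signal over background noise argues for more scatter in dim features. However, the excess was 0.356 (0.21 to 0.51) in the brightest quartile of features too, which counts against noise as the whole cause. After cyclic loess 98.6% of the excess over all tested features was left, which counts against a smooth level-dependent response as its whole cause. That excess is weighted towards dim features. For pairs with replicate 1 the mean SD was 2.27 in the dimmest quartile and 0.98 in the brightest. The excess of the brightest quartile was not measured after cyclic loess, so the test does not cover it. A difference between the muscles, in RNA quality or in labelling remains open and cannot be separated with 1 array per sample; no biological explanation was tested, because the design has 1 group.

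Bright features varied between samples with a median CV of 28.5%. The typical size of the values below 0 predicts a median CV of 2.79% for them, so additive background noise of that size is not a sufficient cause. This prediction used the median size, 204 to 521 over the arrays, and left out a long tail. The 95th percentile of these sizes was 1412 to 8341, and additive errors of the tail were not tested. A level-dependent array response is not a sufficient cause either, as the median CV after cyclic loess was 26.5%. Spot-to-spot error proportional to signal and true differences between the muscles stay open, because the labels name no repeat array of a sample.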

How the results depend on the processing

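Cyclic loess, normexp and the noise-bound filter, and for the correlation also the pseudocount, the added incomplete features and leaving out replicates, were chosen after seeing the data. The count of features with excess spread was 0 under all alternatives but one: it was 4 when arrays were not centred. There limma fitted infinite prior degrees of freedom, against 4.16 in the main analysis, so these 4 calls were made against a different prior. The median CV (38.7%) was 59.7% without centring and 44.7% with features above 0 on 3 or 4 arrays added. For features above the noise bound, with arrays centred on these features, it was 24.3%. After normexp on all features it was 14.1%, and the cause of this was not tested. Leaving out each replicate gave 33.4% to 41.8%, the lowest without replicate 1. The median r between arrays (0.881) was 0.918 without the dimmest quartile, 0.920 with the pseudocount, 0.856 with incomplete features added, 0.899 after cyclic loess, 0.926 after normexp, 0.912 above the noise bound, and 0.860 to 0.885 when each replicate was left out. These values were compared with a jackknife error over samples of 5.72 percentage points for the CV and 0.017 for r. The log2 SDs of the 4 features named in the report stayed within 1.5-fold in 20 of 28 alternatives; that of R559 was 0.11 without replicate 1. Those of R369, R370 and R371, whose alternatives were also added later, did so in 17 of 21: they were 0.95, 0.73 and 1.01 without centring, against 1.62, 1.46 and 1.62, and 0.93 for R370 without replicate 1. No paired analysis was possible because there is 1 group. The planned tests of gene lists were not run, since no gene names were given. Low signal limits the dim features: 524 of 1185 were not above 0 on every array.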

Other observations

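The observations in this part and their tests were chosen after the values were seen. Features with the consecutive IDs R369, R370 and R371 shared a profile in which replicates 1 and 5 were high. Centred intensities of R369 were 38239 and 18757 in replicates 1 and 5, and none of replicates 2 to 4 exceeded 3885. As deposited, R369 was below the noise bound in replicates 2 (6399 against 8341) and 4 (3280 against 4264), so no fold is given for it. For R370 and R371, which were above the bound on all arrays, the lower of the high pair lay 3.26-fold and 3.42-fold above the highest of replicates 2 to 4. As deposited, without centring, replicates 1 and 5 were also the highest, but replicate 1 by much less than after centring. R371 had 532264 and 1766702 there and at most 452336 in replicates 2 to 4. R370 had 149725 and 165637 there and at most 101060. None of the 3 passed the test of excess spread (limma, adjusted p = 0.92). In all, 16 of the 661 features had 2 replicates at least 3-fold above the other 3, and in 5 of them these were replicates 1 and 5. Only 3 of the 16 were above the noise bound on all arrays: R370, R371 and RG229. With smaller folds, some bright features whose IDs do not adjoin these had the same order. R389 had centred log2 intensities of 19.90 and 18.96 in replicates 1 and 5 and at most 18.50 in replicates 2 to 4. For RG467 these were 18.42 and 17.66 against at most 16.93. RG516 and RG378 were high in replicate 1 but not in replicate 5. The 10 brightest features held 47.5% and 47.0% of the intensity in replicates 1 and 5, and 39.0% to 40.4% in the others. R371 was itself the brightest feature in replicates 1 and 5, so this share is not a separate observation. It was not computed without R371.

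Carry-over of signal from R371 is a possible explanation that cannot be told apart from related genes with adjoining IDs. Chance among many features was not excluded, and a shift of bright features as a set in replicates 1 and 5 was not tested. The ratio of R370 to R371 varied 3.03-fold between arrays, which is inside the 5th to 95th percentile (1.44 to 12.5) for random pairs of bright features, and the layout of the arrays is not given in the sources used here. Over all 351 pairs of consecutive tested IDs, the deviations of neighbours correlated across features with a mean r of 0.037 (two-sided permutation p = 0.17), so a tie between neighbours in general was not shown.

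Features at or below 0 tended to be the same on different arrays. All 5 arrays had 36 such features in common, where independent arrays with the observed shares would give 0.276. The profiles of the arrays correlated, so independence was not to be expected and the comparison is a description only. The share of features above 0 on all arrays was 57.0% for IDs starting with R (400 of 702) and 54.0% for IDs starting with RG (261 of 483), a difference that Fisher's exact test did not separate from chance (two-sided p = 0.34). The median CV was 38.0% for tested R features and 41.3% for tested RG features, without regard to level. Within deciles of intensity, the median CV of RG features lay close to that of R features, with a difference of -0.38 percentage points (permutation p = 0.66).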
